A study of Mus musculus with 51 samples.

How the data were processed

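Libraries of polyadenylated RNA were made from about 500 ng of total RNA with a stranded kit, and 50 bp single reads were sequenced on a HiSeq instrument, per the labels' protocols. The mice were male C57, 8 to 12 weeks old, and the ganglia came from lumbar levels 3 to 5, per the labels. Reads were split by sample with bcl2fastq, aligned to the mm9 mouse genome with TopHat2 and counted per gene with HTSeq, per the submitters' processing notes, which gave no versions. The authors deposited 1 table of raw read counts per library, each with 22609 gene symbols and the summary lines that HTSeq adds. These summary lines, which count reads outside genes, ambiguous reads and reads with several alignments, were kept out of the library sizes. Reads that aligned in several places were counted to no gene, so genes with near-identical copies are uncertain. In 15 tables the names of the summary lines began with a low-line sign (_) and in 36 they did not. The 15 were the set B spinal cord tables and the day 35 tables of DRG and paw. The reference annotation at hand was of another build than mm9, so no coordinates are given, and it served only to match symbols and their synonyms, which succeeded for 22398 of 22609 symbols. The labels gave the group and replicate of each library, and where the series description and the library titles disagreed on a day, the titles were used.

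Counts were analysed in R 4.3.3 with edgeR 4.0.16. Within each tissue all libraries entered 1 fit with a coefficient per group. Genes were kept with filterByExpr (smallest count 10, smallest total 15), which left 15333 genes in DRG, 15199 in paw, 15815 in spinal cord and 16304 in the joint fit of DRG and paw. Libraries were scaled with TMM, dispersions were estimated with estimateDisp, and groups were compared with the robust quasi-likelihood fit and its F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 fold change was its size divided by the square root of F. Group means of CPM were computed from the scaled library sizes, CPM of single libraries and over whole tissues from the total gene counts, and log2 CPM used a prior count of 2. Each PTX group of DRG and paw was compared with the vehicle group of its tissue, which was of day 2. In spinal cord, day 1 and day 7 of set A were compared with the vehicle of the same day, and days 22 and 35 of set B with the 6 vehicle libraries of days 1 and 7 together. Further comparisons were set B against set A and against vehicle at day 1, days 22 and 35 against day 1 within set B, vehicle day 7 against vehicle day 1, the PTX effect of day 7 minus that of day 1 in set A, any difference among the 4 PTX days in DRG and in paw, and the DRG effect minus the paw effect at each day.

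Lists of cell type markers and of gene programmes, 39 in all with 562 genes, and the rule for the genes named in the text were written before the data were examined. Of these genes 558 genes matched a symbol of the tables, 11 of them through an older symbol. Each list with at least 5 genes tested was compared with all other genes by camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes. Adjusted p-values of lists were taken over the lists of a comparison. Members were also adjusted over the list alone. These counts are given for lists that camera called in the same data, and members that move together are not separate evidence. They describe a list and are no further test of it.

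The rule for named genes was as follows. For each comparison with vehicle it took the 6 highest and the 6 lowest fold changes among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, without predicted gene models, pseudogenes and immune receptor segments. It added the 10 called list members with the smallest adjusted p, and up to 4 members, by p, of each list called. For comparisons without vehicle it took the 3 highest and 3 lowest. Genes outside this rule are named as chosen after their values were seen. The tissue markers served as a check of the labels.

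The method was tested on simulated counts drawn from the real genes' means and library sizes, with 200 genes changed. At the DRG day 7 comparison, where 15243 simulated genes were tested, edgeR recovered 61.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 97% of those changed 4-fold. At the paw day 22 comparison, with 15092 genes, it recovered 13.4%, 47.8% and 92.4%, and at the difference between DRG and paw at day 7, with 16233 genes, 5.97%, 43.3% and 84.8%. Between 0.943% and 5.88% of its calls were false, against 11.7% to 14.9% with DESeq2 1.42.0. The simulated counts took each gene's spread from edgeR's own fit, so these rates may not hold for the real counts. A planted list of 15 genes was called in each simulation and 0 of 100 random lists were, by camera. The simulated genes were drawn independently of each other, so this cannot show how often camera calls lists whose genes correlate.

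Alternatives were DESeq2 with its own size factors, these size factors within edgeR, no filter on low counts, a threshold of at least 1.5-fold, the replicate number as a block, the mean of a marker list as covariate, only the groups compared in the fit, 1 vehicle day alone for the late spinal cord comparisons, and each library left out in turn. Covariates for sensory neuron, fat cell and hair follicle genes, and tests without the genes at least 4 times higher in DRG than in spinal cord, were added after the data were seen. Libraries were also regrouped in up to 100 other ways, or 60 for the differences between DRG and paw. Overlaps between days were set beside 20 simulations of unchanged groups with the same vehicle libraries. The reported fits carried no block for the replicate number. Upper limits for a count of 0 used 3 counts, and intervals at 95% are exact binomial; both cover counting error only. No reads were at hand, so alignment and counting were not repeated.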

Results

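Polyadenylated RNA was sequenced from 3 tissues of male C57 mice given paclitaxel (PTX), a chemotherapy drug that stabilises microtubules and can damage peripheral nerves, or vehicle. The drug was given as 2 intraperitoneal injections of 2 mg per kg, 1 day apart. The tissues were lumbar dorsal root ganglia (DRG), which hold the cell bodies of the sensory neurons, punch biopsies of the hind paw, which hold the skin those neurons supply, and lumbar spinal cord, where their central branches end. The 51 libraries fell into 17 groups of 3. DRG and paw each had vehicle libraries of day 2 and PTX libraries of days 2, 7, 22 and 35. With vehicle at day 2 only, drug and day (age and collection included) cannot be told apart in DRG and paw at days 7, 22 and 35. The spinal cord libraries came under 2 source names, called here set A (vehicle and PTX at days 1 and 7) and set B (PTX at days 1, 22 and 35, with no vehicle). Titles of the PTX libraries of set A carried the word ipsi, and those of its vehicle libraries the word control. They do not say whether the same side of the cord was taken. The library titles gave day 1 for the earliest spinal cord libraries and were followed here, while the series description gave the same days for every tissue. No label said whether the libraries of a group came from separate animals.

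The reads counted to genes ranged from 18645710 to 27257659 per library in DRG, from 13346971 to 21697763 in paw and from 17661067 to 30247230 in spinal cord. The sensory neuron sodium channel gene Scn10a averaged 1030 ± 203 CPM, the usual unit of counts scaled to library size, in DRG (mean ± SD, n = 15) and 3.75 ± 3.63 (n = 15) in paw. The epidermal keratin gene Krt14 averaged 2290 ± 406 CPM in paw and 5.16 in DRG, and the oligodendrocyte gene Mog averaged 222 ± 57.4 CPM (n = 21) in spinal cord and 0.0862 in DRG. Replicate 2 of the paw vehicle group stood apart, with 44.1 reads outside genes and 156.8 reads with several alignments per 100 gene reads, against at most 23.7 and 116.9 in the other paw libraries. Fold changes below are log2 values with their standard error, from edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment at 0.05. Lists of genes fixed in advance were tested against all other genes with camera at a preset correlation between genes. Of 257 list calls over all comparisons, 7 held with a correlation estimated from the data, and the adjusted p with that estimate stands beside each list below.

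At day 2 after PTX the DRG question was which transcripts respond early. Genes of fat cells stood highest: 7 of the 10 adipocyte genes tested passed when adjusted over the list alone, all higher. The median log2 fold change of the list was 1.73 (camera BH-adjusted p = 3.11e-08, and 0.693 with an estimated correlation). The fat cell hormone gene Adipoq measured 3.85 ± 1.6 CPM with PTX and 0.909 ± 0.584 with vehicle (mean ± SD, n = 3 each). Its log2 fold change of 2.07 ± 0.49 did not pass over all genes (edgeR BH-adjusted p = 0.642). Skeletal muscle genes varied in these libraries too, with list means of 4.66, 4.2 and 3.26 log2 CPM in PTX replicates 1 to 3 and 1.73, 6.24 and 2.5 in vehicle. Vehicle replicate 2 was also the vehicle library highest in fat cell genes (2.17 against 0.72 and 0.9), though below the PTX libraries (2.33 to 2.96). Other tissue around the ganglia is therefore not excluded. Genes of tubulin and its partners, the drug's targets, stood slightly lower, with a median of -0.15 over 22 genes (camera BH-adjusted p = 0.000626, and 0.693 with an estimated correlation). The neuronal tubulin gene Tubb2a alone passed within that list, at -0.28 ± 0.07. No gene of the 15333 tested was called over all genes: edgeR gave a count of 0, with 1168 genes at an unadjusted p under 0.05 where 767 would be expected by chance, and DESeq2 also gave 0.

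At day 7 fat cell genes passed over all genes in DRG. Adipoq rose from 0.909 ± 0.584 to 7.38 ± 1.16 CPM (log2 fold change 3.01 ± 0.48, n = 3 each, edgeR BH-adjusted p = 0.0472). Cyp2e1, which encodes a cytochrome P450 enzyme, rose from 1.16 ± 0.83 to 10.2 ± 1.23 CPM (3.13 ± 0.5, with the same adjusted p). The lipid droplet gene Cidec (3.02 ± 0.5) and the fatty acid carrier gene Fabp4 (2.86 ± 0.46) rose likewise. The lectin receptor genes Clec7a and Clec10a of macrophages and dendritic cells rose by 1.68 ± 0.3 and 1.4 ± 0.23, and the glutamate transporter gene Slc1a2 rose by 0.7 ± 0.13. The pigment enzyme gene Tyrp1 fell from 14.3 ± 1.38 to 6.46 ± 1.26 CPM (-1.15 ± 0.16), and the lipid transporter gene Mfsd2a changed by -0.46 ± 0.08. Of 15333 genes edgeR called 24, 22 higher and 2 lower, with 3438 at an unadjusted p under 0.05 and 866 called by DESeq2. None of the 24 was called in a fit of only the groups compared, which called 0, or with the mean of the fat cell list as covariate, chosen after the result was seen, which called 1. That list holds called genes and lay at 3.35 to 3.6 log2 CPM in the PTX libraries against 0.72 to 2.17 in vehicle. It thus nearly repeats the group, so the loss with this covariate decides no cause. The count of 24 rested on single libraries: it was 0 without vehicle replicate 1 or 3 and 1 without vehicle replicate 2. It was 0 without PTX day 7 replicate 1 or 2, and 1175 without PTX day 7 replicate 3.

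Among the lists at day 7 in DRG, 8 of 10 adipocyte genes passed when adjusted over the list alone and 3 (Adipoq, Cidec and Fabp4) over all genes. The median log2 fold change was 2.91 (camera BH-adjusted p = 1.02e-08, and 0.571 with an estimated correlation). The list's mean lay between 3.35 and 3.6 log2 CPM in the 3 PTX libraries and between 0.72 and 2.17 in the 3 vehicle libraries. Skeletal muscle genes stood at 4.68, 4.14 and 3.71 log2 CPM in PTX replicates 1 to 3 and at 1.73, 6.24 and 2.5 in vehicle. The vehicle library at 6.24 was the one at 2.17 in fat cell genes, so other tissue around the ganglia is not excluded here either. All 11 neutrophil genes tested were higher when adjusted over the list alone and 0 passed edgeR over all genes, with a median of 2.7 (camera BH-adjusted p = 0.000244, and 0.571 with an estimated correlation). The neutrophil calcium-binding gene S100a8 measured 90.7, 476 and 52.5 CPM in PTX day 7 replicates 1 to 3 against 23.3 to 33.6 in vehicle. The cytokine list had 8 of 14 genes higher over the list alone and a median of 0.99 (camera BH-adjusted p = 7.81e-06, and 0.571 with an estimated correlation). Its interleukin gene Il1b changed by 2.88 ± 0.66 without passing over all genes (edgeR BH-adjusted p = 0.076). Of the 18 genes induced by nerve injury, 8 were higher over the list alone, with a median of 0.49 (camera BH-adjusted p = 0.00255, and 0.582 with an estimated correlation). Its neuropeptide gene Npy measured 17.5 CPM in PTX day 7 replicate 2, and 0.697 and 0.306 CPM in the other PTX libraries, against at most 0.143 in vehicle.

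**Figure D1:**
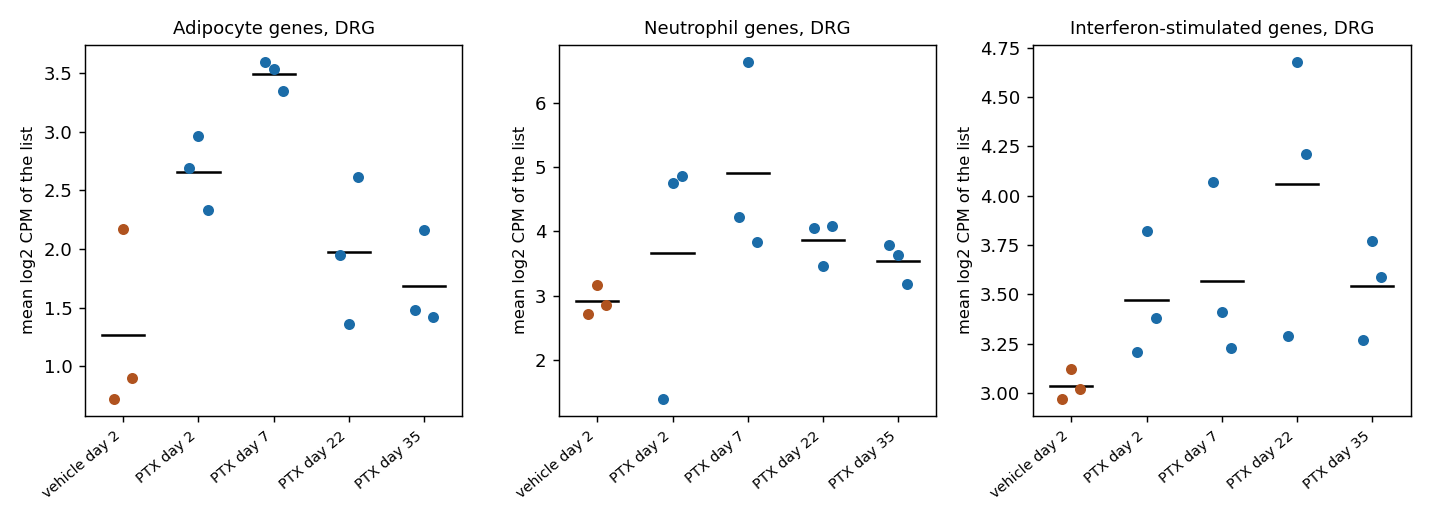
Mean log2 CPM of the adipocyte, neutrophil and interferon lists in each DRG library (points, orange for vehicle and blue for PTX; bars are group means) by group. Adipocyte genes lay between 3.35 and 3.6 in the 3 PTX libraries of day 7, above every vehicle library, and replicate 2 of that group stood highest in neutrophil genes, at 6.65.

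At day 22 genes of the interferon response, the antiviral programme, stood higher in DRG, most clearly in PTX replicates 2 and 3. Of 18 interferon-induced genes, 16 were higher when adjusted over the list alone, with a median log2 fold change of 1.23 (camera BH-adjusted p = 1.58e-15, and 0.559 with an estimated correlation). The RNA sensor gene Ifih1 measured 13.6 ± 1.74 CPM against 8.61 ± 0.795 (n = 3 each), a log2 fold change of 0.66 ± 0.14 that did not pass over all genes (edgeR BH-adjusted p = 0.429). The nucleic acid sensor gene Zbp1 changed by 2.12 ± 0.46 (0.433 by the same test). The list's mean was 3.29, 4.68 and 4.21 log2 CPM in PTX replicates 1 to 3 and 2.97 to 3.12 in vehicle. On the other PTX days it lay above vehicle too, so a rise was not particular to day 22. It was 3.21 to 3.82 at day 2, 3.23 to 4.07 at day 7 and 3.27 to 3.77 at day 35. By fry, 0 lists were called in the day 22 comparison. Cytokine genes also stood higher, with 7 of 14 over the list alone and a median of 0.81 (camera BH-adjusted p = 5.19e-06, and 0.559 with an estimated correlation). Genes that respond to glucocorticoid hormones stood lower, with a median of -0.4 over 13 genes (camera BH-adjusted p = 9.73e-05, and 0.958 with an estimated correlation). Of these Sgk1, Mt1, Mt2 and Fkbp5 passed over the list alone. Over all 15333 genes edgeR called 0, with 1357 at an unadjusted p under 0.05, and DESeq2 called 44. Without PTX day 22 replicate 1 edgeR called 31.

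At day 35 the genes called in DRG included 3 of the circadian clock. The clock gene Per3 rose from 24.6 ± 2.7 to 47 ± 1.14 CPM (log2 fold change 0.93 ± 0.13, n = 3 each, edgeR BH-adjusted p = 0.0059). Arntl, the activator that drives it, fell from 14.5 ± 2.14 to 6.77 ± 0.923 CPM (-1.1 ± 0.14, with the same adjusted p). The clock output gene Hlf rose by 0.77 ± 0.14. Over the list alone 7 of 15 clock genes were higher and 2, Arntl and Npas2, lower, and 3 (Per3, Hlf and Arntl) passed over all genes (median 0.2, camera BH-adjusted p = 0.00871, and 0.77 with an estimated correlation). Tyrp1 fell to 4.77 ± 0.651 CPM (-1.58 ± 0.16, edgeR BH-adjusted p = 0.00121). Slc1a2 rose by 0.72 ± 0.13 and the axon guidance receptor gene Epha5 by 0.64 ± 0.11. The tubulin gene Tuba1b fell from 146 ± 20.9 to 103 ± 4.31 CPM (-0.5 ± 0.09, edgeR BH-adjusted p = 0.0497). Genes with near-identical copies were also called (Rpl23 at -0.56 ± 0.07, Rpl39, Gstp1, Actg1 and Pgk1 lower, Rplp2 and Rps4x higher), and their values are uncertain because reads that align in several places were not counted.

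Of 15333 genes edgeR called 32 in DRG at day 35, 7 higher and 25 lower, with 1987 at an unadjusted p under 0.05 and 157 called by DESeq2. A fit of only the groups compared called 11. Leaving out vehicle replicate 1 or 2 gave 12 or 11 genes, and leaving out PTX day 35 replicate 1, 2 or 3 gave 9, 8 or 5. All day 35 libraries of DRG and paw, and no other library of these tissues, carried another style of summary line in their count tables, so that day 35 and a processing batch cannot be told apart. Of the nerve injury list, Cckbr, Ecel1, Flrt3, Sema6a and Sprr1a were higher over the list alone, named after their values were seen. The list's median was 0.49 (camera BH-adjusted p = 0.00012, and 0.77 with an estimated correlation). Replicate 2 of day 35 stood highest, with a list mean of 4.23 log2 CPM against 3.22 and 3 in replicates 1 and 3 and 2.64 to 2.69 in vehicle.

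**Figure D2:**
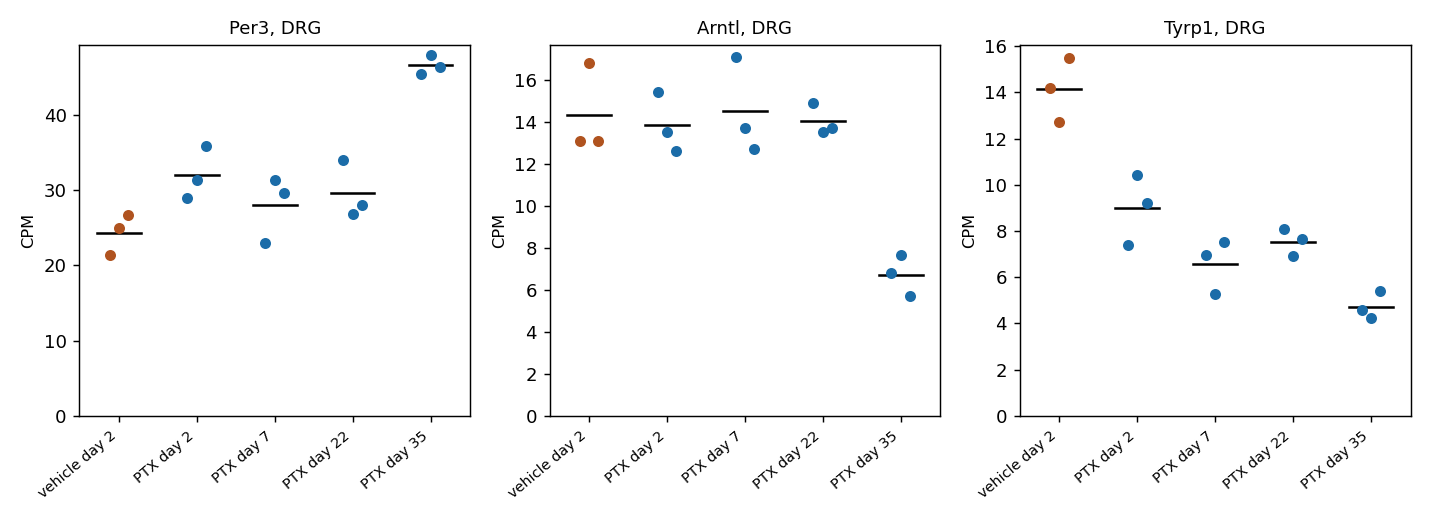
CPM of Per3, Arntl and Tyrp1 in each DRG library (points, orange for vehicle and blue for PTX; bars are group means) by group. At day 35 Per3 lay between 45.4 and 48 CPM against 21.4 to 26.7 in vehicle, and Arntl between 5.71 and 7.65 against 13.1 to 16.8.

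In a test of any difference among the 4 PTX days, edgeR called 3 DRG genes, Rpl23, Rpl39 and Arntl, with 1431 at an unadjusted p under 0.05 and 184 called by DESeq2; these were named after their values were seen. Arntl differed from vehicle by -0.07, -0.03, -0.05 and -1.1 at days 2, 7, 22 and 35 (edgeR BH-adjusted p among the days = 0.0207). Rpl23 differed by 0, 0.16, 0.06 and -0.56 and Rpl39 by 0.14, 0.23, -0.01 and -0.85. The count of 3 was 0 without PTX day 35 replicate 1 or 2, 1 without replicate 3 of that day, and 8 and 6 without PTX day 7 replicates 2 and 3. It was 16 and 5 without PTX day 22 replicates 1 and 3. Days 7 and 35 shared 2 called genes, Slc1a2 (higher) and Tyrp1 (lower), where 0.01 and 0.00326 would be shared if the lists were independent. Both days were compared with the same vehicle libraries, so the lists are not independent. Tyrp1 lay between 4.22 and 10.4 CPM in the PTX libraries of all days, days 2 and 22 included, against 12.7 to 15.5 in vehicle. The fold changes of days 2 and 7 correlated across genes at 0.77, against 0.49 for simulated unchanged groups that share the vehicle libraries, and their covariance was 0.0897 against 0.0326. The other pairs of days correlated less, and days 2 and 22 (0.49 against 0.51) and days 22 and 35 (0.47 against 0.51) lay below the simulated value, although their covariances (0.0426 and 0.0464) lay above the simulated 0.0328. Part of each excess may come from the shared vehicle libraries.

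In the paw at day 2, transcripts of mast cells, the granule cells of allergic reactions in skin, stood higher. Cma1, Cpa3, Mcpt4 and Tpsb2, which encode their proteases, passed when adjusted over the list of 8 alone, and the list's median log2 fold change was 1.17 (camera BH-adjusted p = 1.62e-07, and 0.343 with an estimated correlation). Cma1 measured 25.5 ± 2.74 CPM with PTX and 9.65 ± 3.42 with vehicle (n = 3 each), a change of 1.39 ± 0.29 that did not pass over all genes (edgeR BH-adjusted p = 0.599). Genes of mitochondrial respiration stood lower, 9 of 22 over the list alone, with a median of -0.38 (camera BH-adjusted p = 9.01e-11, and 0.615 with an estimated correlation); Cox7b changed by -0.48 ± 0.14. Skeletal muscle, rich in these transcripts, varied too, with list means of 8.63, 8.75 and 10.38 log2 CPM in PTX replicates 1 to 3 and 10.57, 10.49 and 9.2 in vehicle, so another share of muscle is not excluded. Of 15199 genes edgeR called 0, with 1119 at an unadjusted p under 0.05, and DESeq2 called 37.

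At day 7 in the paw, mast cell, macrophage and connective tissue genes all stood higher. Over the list alone 7 of 8 mast cell genes were higher (median log2 fold change 1.74, camera BH-adjusted p = 1.08e-08, and 0.353 with an estimated correlation). The same held for 16 of 18 myeloid genes (1.12, 5.82e-14 and 0.473, in the same order) and 13 of 18 fibroblast and matrix genes (0.77, 4.55e-10 and 0.514). Cma1 measured 33.4 ± 7.82 CPM against 9.65 ± 3.42 (n = 3 each), a change of 1.78 ± 0.29 (edgeR BH-adjusted p = 0.072). The macrophage growth factor receptor gene Csf1r changed by 1.11 ± 0.24 (0.0989 by the same test). Hair follicle genes had a median of -0.68 over 14 genes (camera BH-adjusted p = 0.000396, and 0.683 with an estimated correlation). Cornified layer genes had a median of -0.35 (camera BH-adjusted p = 0.00437, and 0.741 with an estimated correlation), with list means of 9.35, 9.07 and 8.93 log2 CPM against 9.42 to 9.75 in vehicle, so another mix of epidermis and dermis is not excluded. Of 15199 genes edgeR called 0, with 2091 at an unadjusted p under 0.05, and DESeq2 called 637. Without vehicle replicate 3 edgeR called 6, and without PTX day 7 replicate 1 it called 70.

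At day 22 some mast cell, matrix and myeloid genes of the paw passed over all genes. Col1a1, which encodes the main collagen of the dermis, rose from 803 ± 79.3 to 3140 ± 57.1 CPM (n = 3 each), a log2 fold change of 1.97 ± 0.33 (edgeR BH-adjusted p = 0.0294). The mast cell genes Cpa3 (2.07 ± 0.41), Cma1 (1.77 ± 0.29), Tpsb2 (1.6 ± 0.32) and Fcer1a (2.66 ± 0.55) rose, with Cpa3 at 40.5 ± 12.8 CPM against 9.58 ± 6.86. Other large rises belonged to the chemokine gene Cxcl13 (3.08 ± 0.57), the sialic acid enzyme gene Npl (2.97 ± 0.48), and the myeloid surface receptor genes Cd209f (2.36 ± 0.35) and Cd300ld (2.11 ± 0.46). The fat cell genes Cfd (1.21 ± 0.21) and Cidec (1.24 ± 0.27) rose. Ptgs2, which encodes the prostaglandin enzyme COX-2, fell from 32.2 ± 9.51 to 10.4 ± 2.07 CPM (-1.63 ± 0.25, edgeR BH-adjusted p = 0.0261). The growth factor gene Epgn (-1.45 ± 0.31), the transcription factor gene Meis1 (-0.95 ± 0.18), the kinase gene Sik1 (-0.74 ± 0.16) and the stress gene Sesn1 (-0.53 ± 0.1) fell too. Of 15199 genes edgeR called 170, 159 higher and 11 lower, with 2835 at an unadjusted p under 0.05 and 1298 called by DESeq2. A fit of only the groups compared called 0, and edgeR with DESeq2's size factors called 51. The count was 0 without vehicle replicate 1, without vehicle replicate 2 (the library that stood apart) or without PTX day 22 replicate 2, 20 without vehicle replicate 3, and 1255 without PTX day 22 replicate 3.

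Over the list alone 15 of 18 fibroblast and matrix genes were higher in the paw at day 22, and 5 over all genes (Col1a1, Col1a2, Col5a1, Col6a1 and Sparc). Over the 18 genes the median was 0.96 (camera BH-adjusted p = 6.08e-11, and 0.523 with an estimated correlation). Of the 8 mast cell genes 6 passed over the list alone and 5, the 4 named above and Mcpt4, over all genes (median 1.71, camera BH-adjusted p = 1.36e-07, and 0.512 with an estimated correlation). Of 18 myeloid genes 16 passed over the list alone and the complement gene C1qb (1.58 ± 0.35) over all genes (median 1.21, camera BH-adjusted p = 3.25e-11, and 0.523 with an estimated correlation). Genes of the cornified epidermal layer had a median of -0.62 over 16 genes, none past the test over the list alone (camera BH-adjusted p = 9.21e-05, and 0.586 with an estimated correlation). The activity-induced gene Fosb changed by -1.77 ± 0.4 without passing over all genes (edgeR BH-adjusted p = 0.0535).

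**Figure D3:**
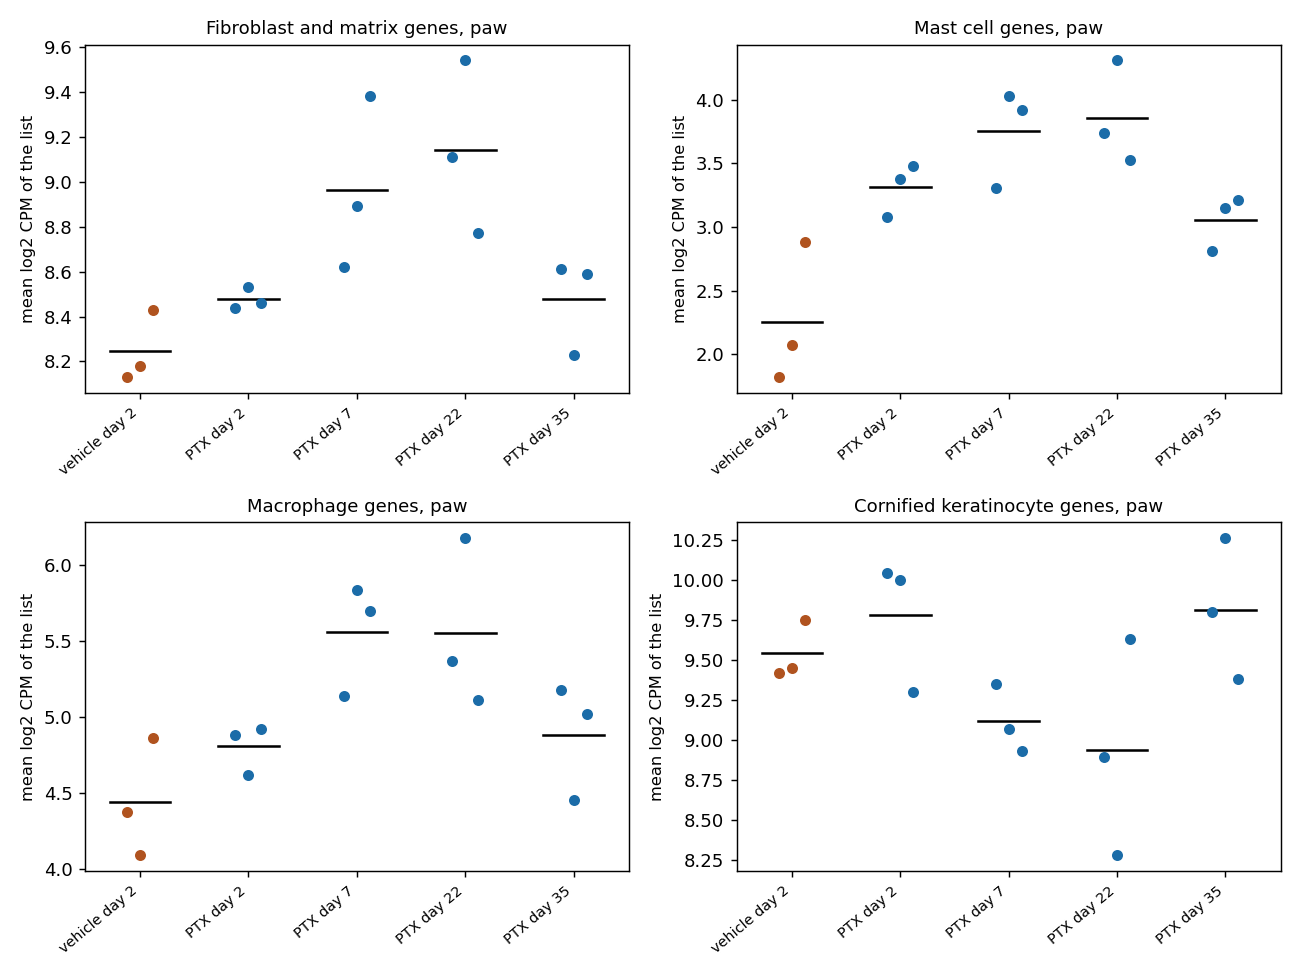
Mean log2 CPM of the fibroblast and matrix, mast cell, myeloid and cornified layer lists in each paw library (points, orange for vehicle and blue for PTX; bars are group means) by group. Mast cell genes lay between 3.53 and 4.31 at day 22 and between 1.82 and 2.88 in vehicle.

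At day 35 Schwann cell genes in the paw, of the glia that wrap nerve fibres, were lower over the list alone in 10 of 15 cases. The median log2 fold change of the list was -0.56 (camera BH-adjusted p = 4.13e-10, and 0.492 with an estimated correlation). The Schwann cell regulator gene Sox10 measured 19.2 ± 7.33 CPM with PTX and 32.6 ± 5.47 with vehicle (n = 3 each), a change of -0.76 ± 0.24 that did not pass over all genes (edgeR BH-adjusted p = 0.893). The list's mean was 5.63, 4.83 and 5.25 log2 CPM in PTX replicates 1 to 3 and 5.65 to 5.97 in vehicle. Replicate 2 was also lowest in skeletal muscle genes (6.13 against 9.2 to 10.94 in the other libraries of the 2 groups) and highest in cornified layer genes (10.26 against at most 9.8), so another mix of tissue in the punch is not excluded. Mast cell genes had a median of 0.68 (camera BH-adjusted p = 0.000126, and 0.492 with an estimated correlation), with list means of 2.81, 3.15 and 3.21 log2 CPM against 1.82, 2.07 and 2.88 in vehicle. Of 15199 genes edgeR called 0, with 807 at an unadjusted p under 0.05 where 760 would be expected by chance, and DESeq2 called 23. In the test among the 4 PTX days edgeR called 0 paw genes, with 2718 at an unadjusted p under 0.05, and DESeq2 called 1627. Without PTX day 22 replicate 3 edgeR called 264 in that test, and without PTX day 7 replicate 1 it called 1. Fold changes of days 7 and 22 correlated across genes at 0.78, against 0.5 for simulated unchanged groups that share the vehicle libraries, with a covariance of 0.174 against 0.0574. The other pairs of days correlated less, and days 2 and 22 (0.34 against 0.5) and days 2 and 35 (0.48 against 0.5) lay below the simulated value, although their covariances (0.0646 against 0.0579 and 0.0708 against 0.0581) lay above it.

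The DRG and paw effects were set against each other by a test of their difference. At day 7 the fat cell genes differed. Cfd was higher in the DRG effect by 2.97 ± 0.63 (edgeR BH-adjusted p = 0.0476) and Cyp2e1 by 2.76 ± 0.54 (0.0406 by the same test). Of 11 adipocyte genes 8 passed over the list alone (median difference 2.12, camera BH-adjusted p = 3.26e-07, and 0.594 with an estimated correlation). At day 22 the mast cell genes Cma1, Cpa3, Fcer1a, Mcpt4 and Tpsb2 had a lower effect in DRG than in paw over the list alone. The list's median was -1.67 over 8 genes (camera BH-adjusted p = 6.73e-07, and 0.144 with an estimated correlation). These genes of the differences were named after their values were seen. On each day at least 1 of the tissues had 0 called genes, so called genes could not overlap. The fold changes correlated across 14243 genes at 0.19, 0.33, 0.21 and 0.16 at days 2, 7, 22 and 35; genes are not independent replicates.

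In the spinal cord, the 3 PTX libraries and 2 of the 3 vehicle libraries of day 1 in set A held transcripts of sensory neurons, whose cell bodies lie outside the cord. Scn10a measured 754, 168 and 303 CPM in PTX day 1 replicates 1 to 3 and 0.383, 245 and 222 CPM in vehicle day 1 replicates 1 to 3. It measured at most 1.53 CPM in the other 15 spinal cord libraries. Between vehicle day 7 and vehicle day 1, with no drug in either, edgeR called 3109 of 15815 genes, 1375 higher and 1734 lower at day 7. The count was 1229, 1522 and 1879 without vehicle day 7 replicates 1 to 3, and 1379 and 1944 without vehicle day 1 replicates 2 and 3. The sensory neuron gene Avil fell from 274 ± 236 to 1.05 ± 0.155 CPM (-8.03 ± 1.26). The neuronal nitric oxide synthase gene Nos1 rose from 0.608 ± 0.38 to 25.4 ± 14.4 CPM (5.38 ± 1.36), each with n = 3. These differences between control days lie within the comparisons of days 22 and 35 below, which took the vehicle libraries of both days together.

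At day 1 the question was the early response of the cord, and genes that respond to glucocorticoid hormones stood higher with PTX. Fkbp5, which encodes a chaperone of the glucocorticoid receptor, measured 88 ± 8.97 CPM in set A with PTX against 39.7 ± 9.95 with vehicle (n = 3 each). This log2 fold change of 1.15 ± 0.18 did not pass over all genes (edgeR BH-adjusted p = 0.0599). Over the list alone 6 of 13 glucocorticoid-responsive genes passed, with a median of 0.47 (camera BH-adjusted p = 1.27e-07, and 0.181 with an estimated correlation). Genes of mitochondrial respiration stood lower, 12 of 22 over the list alone, with a median of -0.26 (camera BH-adjusted p = 3.16e-07, and 0.734 with an estimated correlation). These groups also differed in their content of cord tissue. Mog lay between 59.3 and 181 CPM with PTX and between 154 and 233 with vehicle. Another share of other tissue is therefore not excluded as a part of these list differences. Of 15815 genes edgeR called 0, with 3398 at an unadjusted p under 0.05, and DESeq2 called 174. Without PTX day 1 replicate 2 edgeR called 1782, and without vehicle day 1 replicate 3 it called 10.

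The PTX libraries of day 1 in set B, which held no such sensory neuron transcripts, gave Fkbp5 1.39 ± 0.18 above the vehicle of day 1 (edgeR BH-adjusted p = 0.000786). The lipid droplet gene Plin4 measured 99.4 ± 22.1 CPM against 8.03 ± 3.28 (n = 3 each), a change of 3.62 ± 0.33 (edgeR BH-adjusted p = 2.57e-05). The transcription factor gene Zbtb16 rose by 2.81 ± 0.64. Over the list alone 9 of 13 glucocorticoid-responsive genes were higher (median 0.7, camera BH-adjusted p = 2.41e-07, and 0.116 with an estimated correlation). Lower were 13 of 19 cholesterol synthesis genes (median -0.7, camera BH-adjusted p = 8.02e-08, and 0.246 with an estimated correlation). Schwann cell genes differed between these libraries as well, with list means of 7.93, 9.59 and 7.74 log2 CPM in PTX replicates 1 to 3 of set B and 9.69, 8.63 and 9.64 in vehicle, so peripheral nerve in the pieces is not excluded as a part of this. In this comparison, where set and drug cannot be told apart, edgeR called 1575 genes, 647 higher and 928 lower. The count was 2525, 441 and 682 without vehicle day 1 replicates 1 to 3, and 468, 2832 and 988 without PTX replicates 1 to 3 of set B. The same PTX day of set B and set A differed in 5210 genes, 2928 higher and 2282 lower in set B, with Plin4 at 2.47 ± 0.31 and Scn10a at -8.88 ± 1.43. With the mean of the sensory neuron list as covariate, chosen after the result was seen, this count fell to 1 and that against vehicle to 32. Its gene Scn10a lay between 168 and 754 CPM in the PTX libraries of day 1 in set A and between 0.333 and 1.53 in set B. The covariate thus nearly repeats the set, so the fall to 1 decides no cause. Without the covariate the count of 5210 was 2419 without PTX replicate 1 of set A and 3341 without PTX replicate 3 of set B.

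At day 7 the spinal cord list of glucocorticoid-responsive genes pointed the other way. Hif3a (-1.47 ± 0.28), Klf9 (-0.68 ± 0.16) and Zbtb16 (-2.39 ± 0.63) were lower over the list alone. The list's median was -0.16 over 13 genes (camera BH-adjusted p = 0.0328, and 0.919 with an estimated correlation). None of the 3 passed over all genes (edgeR BH-adjusted p = 0.104 for each). Of 15815 genes edgeR called 0, with 2514 at an unadjusted p under 0.05, and DESeq2 called 626. No library left out changed the count of 0, but a fit of only the 2 groups compared called 1739 genes, 319 higher and 1420 lower.

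At day 22 the cord was compared with the 6 vehicle libraries of days 1 and 7, all of set A, so that day, set and drug cannot be told apart. Epidermal keratin genes stood higher: Krt2 measured 6.67 ± 1.06 CPM (n = 3) against 0.124 ± 0.0763 (n = 6), a log2 fold change of 5.78 ± 0.45 (edgeR BH-adjusted p = 4.89e-06). Krt10 rose by 1.48 ± 0.29. Hrnr, of the same layer, had 0 counts in all 6 vehicle libraries and was at least 10.9-fold higher with PTX, against the upper limit of 3 counts per library that a count of 0 allows. Krt2 lay between 3.72 and 21.5 CPM in all 9 libraries of set B, those of day 1 included, and between 0.0403 and 0.23 in all 12 of set A. The salivary gland genes Smr3a (-5.48 ± 0.83) and Bpifa2e (-5.58 ± 0.9), the water channel gene Aqp1 (-3.1 ± 0.6) and the imprinted gene H19 (-2.48 ± 0.5) were lower. Of 15815 genes edgeR called 68, 36 higher and 32 lower, with 3741 at an unadjusted p under 0.05 and 1253 called by DESeq2. The choice of vehicle day moved the count, to 6 with vehicle day 7 alone and 3179 with vehicle day 1 alone, and a fit of only the groups compared called 1079. With vehicle day 7 alone Aqp1 changed by -1.17 and H19 by -0.8, and with vehicle day 1 alone by -5.04 and -4.16. The count was 15, 12 and 42 without vehicle day 7 replicates 1 to 3, 673 without vehicle day 1 replicate 1, and 6, 8 and 8 without PTX day 22 replicates 1 to 3. The cornified layer list, with 7 of 8 genes higher over the list alone and 3 (Krt2, Hrnr and Krt10) over all genes, held with an estimated correlation (camera BH-adjusted p = 8.15e-12, and 0.0229 with it). Fibroblast and matrix genes were lower, 15 of 18 over the list alone, with a median of -1.39 (camera BH-adjusted p = 5.58e-09, and 0.451 with an estimated correlation). Their list mean was 6.07 to 6.5 log2 CPM in vehicle day 1, 5.21 to 5.5 in vehicle day 7 and 4.46 to 4.67 at day 22. Schwann cell genes, of nerve roots and ganglia, moved with them (8.63 to 9.69, 7.65 to 8.63 and 7.18 to 7.75), so other tissue in the dissected pieces is not excluded.

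At day 35 the cord was compared with the same 6 vehicle libraries, and again day, set and drug cannot be told apart. Ptgs2 rose from 2.1 ± 1.6 (n = 6) to 10.1 ± 3.46 CPM (n = 3), a log2 fold change of 2.53 ± 0.43 (edgeR BH-adjusted p = 0.0137). The bacterial sensor gene Cd14 of microglia and macrophages rose from 3.36 ± 0.688 to 7.17 ± 0.556 CPM (1.1 ± 0.14, edgeR BH-adjusted p = 0.00161). The oxysterol enzyme gene Ch25h rose by 2.34 ± 0.36, the chemokine gene Cxcl1 by 3.11 ± 0.57 and the early response gene Ier3 by 0.76 ± 0.13. None of these 5 genes was among the genes called at day 35 against day 1 within set B, although the cytokine list was higher there. Krt2 rose by 6.49 ± 0.44, and Hrnr was at least 24.8-fold higher against the limit of 3 counts per library. Smr3a (-6.58 ± 0.91), Bpifa2e (-5.91 ± 0.92), the glial gene Fabp7 (-1.01 ± 0.2) and the cholesterol synthesis gene Dhcr7 (-0.47 ± 0.1) were lower. Fabp7 is also a gene of peripheral glia. Such genes were taken as a share of their DRG level, beyond the mean of the cord libraries outside day 1 of set A. This share was 10.4% to 64.3% in the vehicle libraries of day 1 and -11.6% to 4.95% in those of day 7. In PTX day 35 replicates 1 to 3 it was 12.8%, -14.2% and 32.1%. Over the list alone 11 of 19 cholesterol synthesis genes were lower (median -0.4, camera BH-adjusted p = 4.29e-10, and 0.151 with an estimated correlation). Of 13 glucocorticoid-responsive genes 8 were higher (0.42, 4.52e-07 and 0.103 in the same order). In this comparison 1 of the 17 lists called, neither of these 2, held with an estimated correlation. Of 15815 genes edgeR called 59, 37 higher and 22 lower, with 2031 at an unadjusted p under 0.05 and 382 called by DESeq2. The edgeR count was 28 with vehicle day 7 alone, 1381 with vehicle day 1 alone and 13 in a fit of only the groups compared. The count was 35 without vehicle day 7 replicate 2, 674 and 38 without vehicle day 1 replicates 1 and 2, and 18, 30 and 21 without PTX day 35 replicates 1 to 3. Days 22 and 35 shared 12 genes called higher and 11 called lower, where 0.0842 and 0.0445 would be shared if independent and 0 were in 20 simulations of unchanged groups. Neither value allows for the difference between the sets, which lies within both comparisons. Krt2 and Hrnr, 2 of the shared genes, were higher in every library of set B than in every library of set A. Srp54a (higher) and Rpl23 (lower) were also shared. At both days they kept an adjusted p under 0.05 in 17 other fits, DESeq2 and each library left out among them. So did Krt2, but not Aqp1 and H19 at day 22 or Ptgs2 and Cxcl1 at day 35. Rpl23 has near-identical copies, so its values are uncertain. Set B tables alone in spinal cord had summary lines with a low-line sign, so a counting difference is not excluded for Srp54a and Rpl23.

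**Figure D4:**
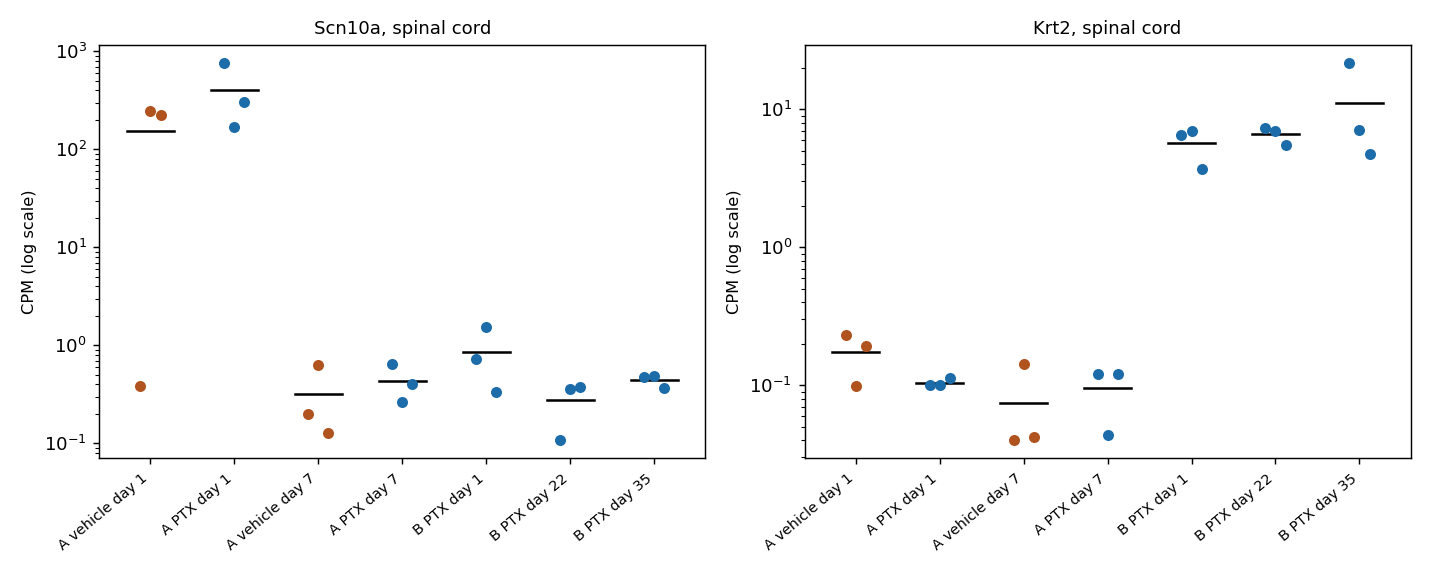
CPM on a log axis of the sensory neuron gene Scn10a and the epidermal gene Krt2 in each spinal cord library (points, orange for vehicle and blue for PTX; bars are group means) by group. Scn10a exceeded 1.53 CPM in 5 libraries, all of day 1 in set A, and Krt2 lay between 3.72 and 21.5 CPM in every library of set B.

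Within set B, day 22 was set against day 1, both with PTX. Plin4 fell from 99.4 ± 22.1 to 5.27 ± 0.759 CPM (n = 3 each), a log2 change of -4.23 ± 0.34 (edgeR BH-adjusted p = 4.98e-06). Fkbp5 changed by -1.62 ± 0.19, and the metallothionein gene Mt2 by -1.37 ± 0.14. All 13 glucocorticoid-responsive genes were lower over the list alone and 9 over all genes, with a median of -1.37 (camera BH-adjusted p = 1.8e-22, and 0.00198 with an estimated correlation). Interferon-induced genes were lower in 13 of 18 cases over the list alone (median -1.21, camera BH-adjusted p = 1.48e-06, and 0.575 with an estimated correlation). Their list means were 1.53, 2.93 and 3.57 log2 CPM in PTX day 1 replicates 1 to 3 and 1.64, 1.98 and 1.72 at day 22, so replicates 2 and 3 of day 1 carried the difference. The myelin gene Opalin rose from 22.8 ± 0.634 to 60.9 ± 5.47 CPM (1.42 ± 0.27, edgeR BH-adjusted p = 0.0122). In all edgeR called 172 genes, 31 higher and 141 lower. Without PTX day 1 replicate 2 it called 110, and without PTX day 22 replicates 1, 2 and 3 it called 61, 82 and 107.

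Day 35 against day 1 within set B gave 14 genes, 1 higher and 13 lower. Plin4 fell to 14.1 ± 4.35 CPM (-2.82 ± 0.31, edgeR BH-adjusted p = 0.000581), and Fam83d (-1.37 ± 0.17) and the tight junction gene Cldn14 (-1.2 ± 0.16) were lower. The glucocorticoid-responsive list had a median of -0.4 (camera BH-adjusted p = 1.18e-09, and 0.026 with an estimated correlation), with Mt1 and Mt2 past the test over all genes. B cell genes stood higher, 6 of 9 over the list alone, with a median of 1.79 (camera BH-adjusted p = 2.57e-11, and 0.026 with an estimated correlation). So did 4 of 14 cytokine genes (median 0.54, 5.2e-09 and 0.026 in the same order). The satellite glia list stood lower, 2 of 10 genes over the list alone (median -0.13, 0.00188 and 0.026). It shares Slc1a3, Gja1 and Glul with the astrocyte list, so in cord this call cannot be given to satellite glia. The count was 3 and 7 without PTX day 35 replicates 1 and 2.

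**Figure D5:**
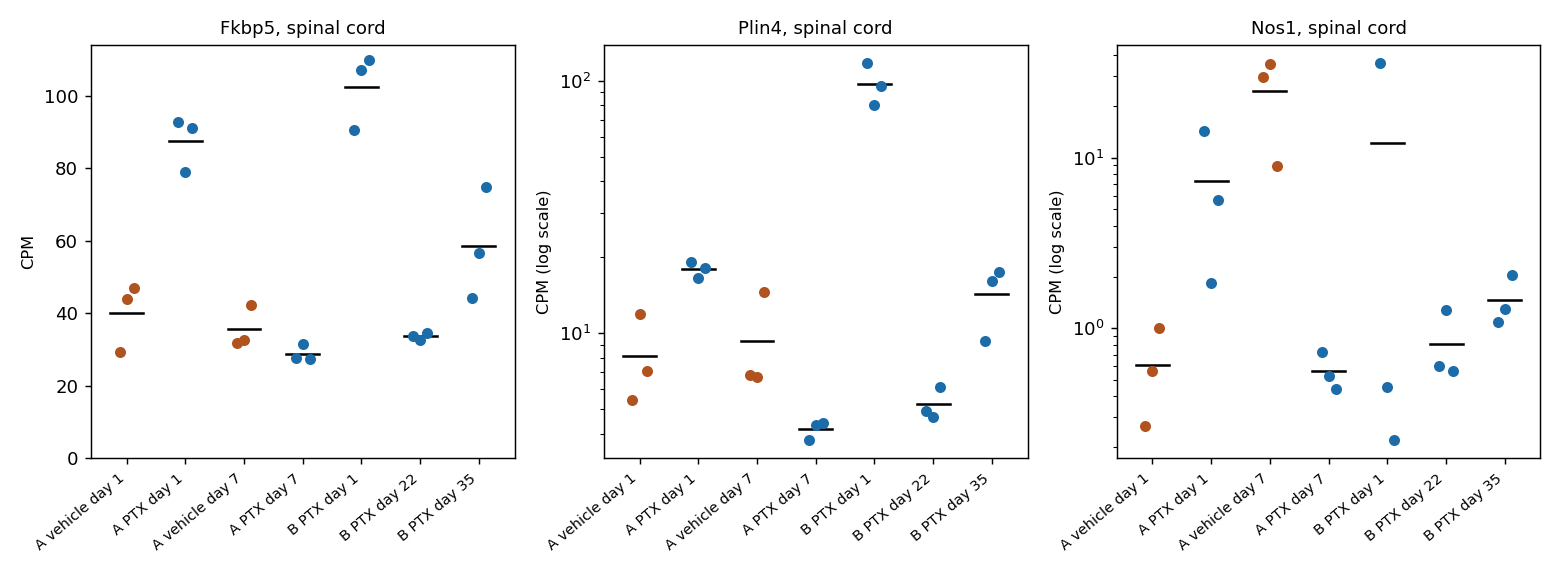
CPM of Fkbp5 (linear axis), Plin4 and Nos1 (log axes) in each spinal cord library (points, orange for vehicle and blue for PTX; bars are group means) by group. Fkbp5 lay between 79.1 and 110 CPM in the 6 PTX libraries of day 1 and between 29.4 and 46.9 in the vehicle libraries of that day.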

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

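The tests on sensory neuron transcripts in this part were chosen only after the result was seen; the regroupings of the libraries were planned.

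The PTX effect on glucocorticoid-responsive genes in the spinal cord differed between days 7 and 1 of set A, by a test of the difference itself. Day 7 minus day 1 was -1.52 ± 0.26 for Fkbp5 (edgeR BH-adjusted p = 0.0134), -2.92 ± 0.38 for Hif3a, -1.42 ± 0.23 for Klf9 and -4.95 ± 0.9 for Zbtb16, the 4 members called over all genes, named after their values were seen. The list's median was -0.91 (camera BH-adjusted p = 2.8e-05, and 0.62 with an estimated correlation). In all, 1386 genes differed, 458 with a higher and 928 with a lower effect at day 7, and DESeq2 called 2304. With 1 of 100 regroupings, the real one, reaching this count and 9 as the highest of the others, a random grouping of the libraries can be excluded as its source. The count was 20, 102 and 860 without PTX day 7 replicates 1 to 3, and 208 and 220 without vehicle day 7 replicates 1 and 2. It was 214, 3188 and 824 without PTX day 1 replicates 1 to 3, and 668 and 323 without vehicle day 1 replicates 1 and 2.

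This difference rests on the day 1 libraries of set A, of which 5 held sensory neuron transcripts. Shares of the DRG level were taken beyond the mean of the cord libraries outside day 1 of set A, as the median over genes. Over 17 sensory neuron genes the share was 61.7%, 19.1% and 35% in PTX replicates 1 to 3 and 30.9% and 27.2% in vehicle replicates 2 and 3. Scn10a reached 754 CPM and Avil averaged 274 CPM in vehicle. PTX as the source is argued against by the 2 vehicle libraries that held them. Other genes enriched in DRG had 1.14 times the share of the sensory neuron genes in the median library, between 1.07 and 1.17 in all 5, so transcripts of DRG neurons may have come over as a whole. Ganglion tissue in the dissected piece stays open: the glial share was 2.06 times the neuronal share in the median library, but between 0.337 and 2.48, and vehicle replicate 1 had a glial share of 61.5% with none of the neuron genes. With the sensory neuron list as covariate 108 genes differed.

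At day 7 the DRG effect differed from the paw effect in 32 genes, 13 higher and 19 lower in DRG. The adrenergic receptor gene Adrb3 of fat cells (4.31 ± 0.74, edgeR BH-adjusted p = 0.0299), the fatty acid enzyme gene Acsm3 (3.51 ± 0.61), Cyp2e1 and Cfd were higher. The synapse scaffold gene Dlg4 (-1.03 ± 0.18) and the endosome gene Nsg1 (-1.23 ± 0.25) were lower, chosen after their values were seen. Of 60 regroupings 5 gave as many genes, with 260 as the highest other count, so chance is not excluded. The count was 0 and 3 without DRG vehicle replicates 1 and 3, and 9, 0 and 14 without paw vehicle replicates 1 to 3. It was 0, 0 and 13 without DRG PTX replicates 1 to 3, and 192, 4 and 3 without paw PTX replicates 1 to 3. DESeq2 called 346.

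At day 22 the effects differed in 4 genes, named after their values were seen: Ptgs2 at 4.15 ± 0.7, Abcg2 at -0.81 ± 0.14, Glb1 at -0.85 ± 0.15 and Nsg1 at -1.59 ± 0.25 in DRG minus paw (edgeR BH-adjusted p = 0.0273 for each). Ptgs2 fell in paw by 1.63 and measured 1.67 ± 1.21 CPM in DRG against 0.302 ± 0.238 in vehicle (n = 3 each). As many genes arose in 6 of 60 regroupings, with 70 as the highest other count, so chance is not excluded, and DESeq2 called 260. The count was 0, 1 and 0 without DRG vehicle replicates 1 to 3, 0, 0 and 8 without paw vehicle replicates 1 to 3. It was 0 without DRG PTX replicate 2 or 3, and 19, 1 and 722 without paw PTX replicates 1 to 3.

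At day 35 they differed in 3 genes, named after their values were seen: 1810041L15Rik at 1.21 ± 0.19, the cell adhesion gene Cadm2 at 1.05 ± 0.18 and the GABA transporter gene Slc6a11 at -4.46 ± 0.75 (edgeR BH-adjusted p = 0.0216 for each). As many arose in 8 of 60 regroupings, with 12 as the highest other count, and DESeq2 called 13. The count was 0 without DRG vehicle replicate 1, DRG PTX replicate 3, paw vehicle replicate 1 or paw PTX replicate 3, and 1 without DRG PTX replicate 2, paw vehicle replicate 2 or paw PTX replicate 2. At day 2 edgeR called 0 genes, with 988 at an unadjusted p under 0.05, DESeq2 called 0, and all 60 regroupings gave 0.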

How the results depend on the processing

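The covariates for sensory neuron, fat cell and hair follicle genes and the tests without genes enriched in DRG were chosen only after the result was seen; the other alternatives were planned. Where a count moved, the cause was not tested unless the alternative names it (fewer libraries or genes).

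With DESeq2 the counts were 866, 44 and 157 in DRG at days 7, 22 and 35, and 184 among the DRG days. They were 37, 637, 1298 and 23 in paw at days 2, 7, 22 and 35, and 1627 among the paw days. In spinal cord they were 174, 626, 1253 and 382 at days 1, 7, 22 and 35, and 401 and 57 for days 22 and 35 against day 1 in set B. They were 2304 for day 7 minus day 1, and 346, 260 and 13 for DRG minus paw at days 7, 22 and 35. On simulated data 11.7% to 14.9% of DESeq2's calls were false. Those counts took their spread from edgeR's own fit. At DRG day 7 DESeq2 recovered 62.7% of simulated 1.5-fold changes and edgeR 61.2%, while on the real counts they called 866 and 24 genes. The simulation does not reproduce this gap, so it cannot say which count is nearer the truth. Its size factors within edgeR gave 51 in paw at day 22 and 17 for DRG minus paw at day 7. Without a filter on low counts the spinal cord gave 45 at day 22. A threshold of 1.5-fold gave 14 and 18 in DRG at days 7 and 35 and 43 in spinal cord at day 22.

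Fits of only the groups compared, which estimate the spread from fewer libraries, gave 0 and 11 in DRG at days 7 and 35, and 203, 0 and 1 in paw at days 7, 22 and 35. They gave 1739, 1079 and 13 in spinal cord at days 7, 22 and 35. The 1739 were 319 higher and 1420 lower. The planned marker covariates gave 1729 and 64 in DRG at days 7 and 35, 67 and 899 in paw at days 7 and 22, and 10 and 469 in spinal cord at days 22 and 35. The fat cell covariate, which nearly repeats the group there, gave 1 in DRG at day 7. With vehicle day 1 alone the spinal cord gave 3179 and 1381 at days 22 and 35, and with vehicle day 7 alone 6 and 28. The sensory neuron covariate gave 7, 5 and 18 in spinal cord at days 1, 22 and 35. It gave 32 and 1 for set B against vehicle and against set A, 23 for day 35 against day 1, 80 for vehicle day 7 against day 1, and 108 for day 7 minus day 1. Under it Scn10a in set B against set A reversed to 0.45 (edgeR BH-adjusted p = 0.779, against 1.03e-11 with DESeq2 to 0.00734 under its other alternatives). Scn10a is a member of that list, which nearly repeats the set in this comparison, so the fall to 1 decides no cause. Without genes enriched in DRG the spinal cord gave 27 and 36 at days 22 and 35.

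The replicate number as a block gave 155 in DRG at day 7, 75 in paw at day 22, 1, 41 and 36 in spinal cord at days 1, 22 and 35, and 11 for DRG minus paw at day 7. Its other counts stayed within 1.5 times. In none of the comparisons did every same-numbered pair of the groups compared correlate over 0.1, so the numbers were not taken to pair the libraries. Among the DRG PTX groups of days 2, 7 and 35 every such pair did, at 0.182 to 0.473, so a batch shared by number stays open there. Correlations of same-numbered libraries ran from -0.593 to 0.473 in DRG (16 of 30 over 0.1), from -0.607 to 0.629 in paw (7 of 30) and from -0.707 to 0.543 in spinal cord (27 of 63). Differently numbered libraries reached 0.592, 0.706 and 0.591, so not every library correlated best with its own number.

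Leaving out 1 library at a time gave these ranges, with the libraries named beside each result in the other parts. DRG gave 0 to 0 at day 2, 0 to 1175 at day 7, 0 to 31 at day 22, 5 to 29 at day 35 and 0 to 16 among the days. Paw gave 0 to 0 at days 2 and 35, 0 to 70 at day 7, 0 to 1255 at day 22 and 0 to 264 among the days. Spinal cord gave 0 to 1782 at day 1, 0 to 0 at day 7, 6 to 673 at day 22, 18 to 674 at day 35, 441 to 2832 for set B against vehicle and 2419 to 6181 for set B against set A. It gave 61 to 220 and 3 to 17 for days 22 and 35 against day 1, 1229 to 3429 for vehicle day 7 against day 1 and 20 to 3188 for day 7 minus day 1. DRG minus paw gave 0 to 1, 0 to 192, 0 to 722 and 0 to 3 at days 2, 7, 22 and 35.

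Of 257 list calls by camera, 7 held with an estimated correlation. By its own test fry called 57 lists, not all of them among the 257. Of 171 named gene results 138 kept their side of the threshold with the block and 154 with DESeq2's size factors in edgeR. With DESeq2 itself 143 of 168 did, and the other 25 passed there and not in edgeR as reported. Leaving out 1 library at a time gave 1263 cases, each a named gene result in 1 such fit. Of these 796 kept their side, 452 no longer passed, 15 newly passed, and no direction changed. The cases overlap, since each gene result enters several times. Pairs of replicates differed by more than counting error in all 51 cases (chi-square per degree of freedom 5.48 to 231).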

Other observations

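The tests on day 35, on the clock and on the dermis in this part were chosen only after the result was seen; those on muscle and hair follicle and the regroupings of the libraries were planned.

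Some neuronal genes, named after their values were seen, lay far apart between spinal cord groups, and within some groups between libraries. Nos1 lay between 8.9 and 35.5 CPM in the vehicle libraries of day 7 and between 0.442 and 0.725 in the PTX libraries of that day. The glycine transporter gene Slc6a5 lay between 5.99 and 108 CPM against 1.57 and 1.81, and the vesicle traffic gene Rab11fip4 between 114 and 143 against 9.31 and 12.2. None of these 3 genes passed edgeR over all genes at day 7. The vehicle libraries of day 1 were low as well, with Rab11fip4 between 6.71 and 7.37, while the PTX libraries of day 1 in set B ran from 8.49 to 148. The GABA and glycine vesicle transporter gene Slc32a1 stayed between 218 and 261 CPM in vehicle and 268 and 286 with PTX at day 7, and the GABA synthesis gene Gad1 between 197 and 246 and between 246 and 249.

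In paw at day 35 the potassium channel genes Kcna1, at 45.6 ± 10.5 CPM against 85.6 ± 7.43 (n = 3 each), and Kcna2, both chosen after their values were seen, changed by -0.91 ± 0.19 and -0.78 ± 0.19 without passing over all genes (edgeR BH-adjusted p = 0.552 and 0.707). Neutrophil genes in paw varied by library, with list means of -0.56, 2.07 and 4.2 log2 CPM in PTX day 22 replicates 1 to 3. In DRG the same list stood at 1.39 in PTX day 2 replicate 1 and at 4.76 and 4.86 in replicates 2 and 3. Skeletal muscle transcripts reached the cord libraries unevenly, with Ckm at 124 ± 174 CPM over the 6 vehicle libraries and 3.23 ± 2.18 in the PTX libraries of day 35.

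The genes changed in DRG at day 35 were all measured in tables whose summary lines began with a low-line sign. A counting difference shared by all such tables is argued against. In spinal cord the mean of the set B groups was set against day 7 of set A. Of the 30 called genes other than Rpl23 that were tested there, 26.7% (exact 95% interval 12.3 to 45.9) went the same way, against 45.4% of all genes. The interval treats genes as independent, which they are not. For Rpl23 alone such a counting difference stays a candidate explanation, since Rpl23 differed by -0.75 in that comparison too. A library batch of the day 35 samples alone cannot be told apart from the day. The same way went 93.5% of the called genes, 29 of 31, in paw at day 35, which a batch and a lasting effect would both give. For the clock genes, collection at another time of day is consistent with the paw value, where Per genes moved 0.51 above Arntl and its partners on the log2 scale, just past a bound of 0.5 set after the data were seen. This is weak evidence, since the same difference was -0.53 between vehicle days 7 and 1 in spinal cord, with no drug in either, and -0.35 in paw at day 7. The labels give no time of collection, and an effect of the drug on the clock stays open.

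The genes raised in paw at day 22 could reflect another mix of tissue in the punch. Muscle and hair follicle are argued against, since the median fold change of the 159 higher genes with either list as covariate was 0.999 and 1 times that without. Both lists lay at similar levels in the groups, which weakens the test. A larger share of dermis cannot be told apart from more cells or matrix per dermis. The endothelial, Schwann cell and sweat gland lists had medians of 0.53, 0.06 and -0.21, with 0.06 in the middle, on bounds set after these were seen. Biologically, growth of mast cells, macrophages and matrix after PTX stays untested.

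Regrouping the libraries of a comparison showed how often other splits gave as many genes. Groups of 3 against 3 have 10 splits, too few for a share under 0.05. The real count and the highest other count were 0 and 44 in DRG at day 2, 24 and 15 at day 7, 0 and 133 at day 22, and 32 and 0 at day 35. In paw they were 170 and 0 at day 22, and 0 and 0 at days 2, 7 and 35. In spinal cord they were 0 and 0 at days 1 and 7. They were 1575 and 864 for set B against vehicle, 5210 and 748 for set B against set A, 172 and 0 for day 22 against day 1, and 3109 and 192 for vehicle day 7 against day 1. They were 14 and 579 for day 35 against day 1, where 2 of 10 splits gave as many. For spinal cord days 22 and 35, 9 and 10 of 84 splits gave as many genes as the real 68 and 59, with 4433 and 3352 as the highest others, so chance is not excluded. The highest splits put the 3 vehicle libraries of day 1 together, a structure of the samples. Among the DRG days 3 of 100 splits, the real one included, gave 3 genes, which was also the highest other count. Other splits thus tied with the real one, and 100 drawn splits give the share only roughly, so chance is not excluded. Among the paw days all 100 gave at least the real 0, with 3247 as the highest.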
